A study of Mus musculus with 2 samples.

How the data were processed

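Total RNA of C2C12 cells was profiled by long-read sequencing in 2 libraries, given in the labels as biological replicates 1 and 2 of 1 group. Per the file headers, the deposited transcript tables hold the raw count of reads per transcript model, with no normalisation, and list only models with at least 1 read. The deposited annotations hold the mm10 coordinates of each model. Alignments were made on mm10 and annotated by the authors against GENCODE M21 per the file headers, and unannotated models carry the name of TALON as their source. The aligner, its version and the filters are not given in the sources used here. Sequence alignments of the reads were not used here. Depth was 791850 reads in replicate 1 and 735077 in replicate 2. Of these, 773408 and 722647 lay on annotated genes, over which 3 counts make 3.88 and 4.15 CPM.

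A gene's count was the sum over all models assigned to an annotated gene, and CPM were taken over all annotated-gene reads. Where 12 symbols had 2 identifiers, the identifiers were kept apart, and the one with more reads was used for lists. Gene coordinates came from GENCODE M21 on mm10. Complete models were the annotated class and the unannotated classes NIC and NNC. These classes do not establish that a model spans a whole transcript. Unannotated structures with several exons were matched between libraries by chromosome, strand and exact intron chain, since their identifiers belong to a single library. Shares of reads are given with Wilson 95% intervals, which cover counting error only.

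The series has 1 group, so no condition could be compared, and every test compared the 2 libraries. Genes with at least 10 reads summed over both were tested by a two-sided exact binomial test of replicate 2 against replicate 1, given the library totals, with Benjamini-Hochberg adjustment at 0.05. Log2 ratios used an offset of 0.5 reads, and a second count required at least 2-fold. The biological coefficient of variation came from edgeR with TMM scaling and an intercept only. Isoform use was tested per gene by a two-sided Fisher's exact test of the most used transcript against all other complete models, in genes with at least 20 complete-model reads in each library. A model counted as seen in the other library from at least 5 reads in one and 1 in the other. An isoform counted as used at 10% or more. For each gene list the median log2 ratio of log2(CPM + 1) values was placed among 10000 random lists of the same size matched on mean expression, and lists outside percentiles 2.5 to 97.5 were named as apart. The adjustment of these percentiles over the lists was added after they were seen.

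The comparisons, the tests, the 23 gene lists with 325 distinct genes and the alternatives were chosen before the data were examined. The lists covered myogenic transcription factors, inhibitors of myogenic differentiation, myoblast surface and fusion genes, contractile genes, the cytoskeleton, extracellular matrix, cell cycle, cell cycle inhibitors, glycolysis, translation factors, mitochondrially encoded mRNAs, splicing regulators, long non-coding RNAs, imprinted genes, stress and immediate early genes, 7 sets of markers of other cell types and isoform genes. Genes were named by rule. These were the 15 highest genes, all members with reads of lists of up to 13 genes and the 4 highest of longer lists, and the 6 genes per direction with the smallest adjusted p among 2-fold differences. To them came the 10 unannotated structures with the highest lower count, 12 isoform genes with the most complete-model reads, 5 unannotated loci and 5 genes of the isoform test. Members with 0 reads were named or only counted. The level of 1 member of the myogenic transcription factor list is not reported here. Named outside the rule, after their values were seen, were Tnnc2, Timp2, Pgk1, Pgam1, Mt1, Qk, Mbnl2, the list members outside the rule whose calls changed under an alternative, and the parent genes Gapdh, Hspa8, Rpl3 and Rps2 with their pseudogenes.

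The tests of genes and isoforms were tried on simulated reads of the same depth, drawn with counting error alone. Few false calls were thus built in, and these runs do not measure false calls under the wider spread of the real libraries. Of 8912 simulated genes tested, 197 were changed 2-fold. The binomial test called 68 of these (34.5%), and 57 of 64 of those with at least 100 reads. It also called 3 unchanged genes. Of genes changed 4-fold it called 157 of 200, with 5 unchanged genes called. Fisher's test called 139 of 200 genes whose main transcript was moved by 30 points and 0 others. The list percentile was tried on the real ratios of random genes, which leaves out genes that vary together. It set apart 35 of 40 lists of 26 genes moved by 0.3 on the log2 scale, and 1 of 40 unmoved lists.

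Alternatives covered TMM and DESeq2 scaling, filters of no reads or 50 reads, complete models alone, pseudocounts of 0.1 and 10, other read minimums for models and isoforms, matching by identifier, all models with incomplete ones and leaving out each replicate. Processed pseudogenes were compared with protein-coding transcripts by blastn at 98% identity over 90% of their length. Tools were Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and blastn 2.17.0+.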

Results

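Transcript structures of C2C12 cells, a mouse myoblast line, were measured by long-read sequencing of total RNA in 1 group of 2 biological replicates. The labels trace the line to crushed thigh muscle of C3H mice. The labels do not give the differentiation state of the culture or the sequencing platform. The deposited tables gave raw read counts per transcript model, 791850 reads on 82272 models in replicate 1 and 735077 reads on 78691 models in replicate 2. Annotated genes took 97.7% and 98.3% of these reads, and 93.9% and 94.4% of the annotated-gene reads lay on protein-coding genes. Gene levels are given in CPM over annotated-gene reads, as mean ± SD with n = 2. A gene with 0 reads could have reached 3.88 CPM in replicate 1 and 4.15 CPM in replicate 2 (3 counts). Intervals, floors and the p-values of single genes cover counting error only.

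The first question was which genes this myoblast line expressed. Reads fell on 13029 annotated genes in replicate 1 and 12888 in replicate 2. Both libraries held 11719 genes, of which 10785 were protein-coding, and 8314 had at least 5 reads in each. Transcripts for a secreted lectin, iron storage, the cytoskeleton and a bone matrix phosphoprotein led the list. Lgals1 (ENSMUSG00000068220.6; mm10 chromosome 15, 78926725 to 78930465), which encodes galectin-1, had the highest mean at 9181 ± 1575 CPM. The ferritin chains Ftl1 (chromosome 7, 45457944 to 45459884) and Fth1 (chromosome 19, 9980598 to 9985098) stood at 7079.5 ± 157 and 5122 ± 314 CPM. Actb (chromosome 5, 142903115 to 142906754), beta-actin, stood at 6609.8 ± 2657 CPM, Actg1, gamma-actin, at 5321 ± 645 CPM and Vim, the intermediate filament vimentin, at 5231 ± 634 CPM. Spp1 (chromosome 5, 104435118 to 104441050), which encodes osteopontin, stood at 5989 ± 199 CPM. The ribosomal stalk gene Rplp0 had 5066 ± 153 CPM and the elongation factor Eef1a1 4564 ± 311 CPM. The glycolytic enzymes Pkm and Eno1 had 4279 ± 499 and 4170.3 ± 445 CPM. Anxa2, a calcium-dependent membrane-binding protein, had 4153 ± 352 CPM and Tmsb10, an actin-monomer-binding peptide, 3676 ± 1054 CPM. The processed pseudogenes Gm15459 (chromosome 5, 5781615 to 5783555) and Rpl3-ps1, at 5064 ± 789 and 4942 ± 369 CPM, completed the top 15. Gm15459 is near-identical to Hspa8, which encodes a constitutive heat shock protein and had 173 ± 27.2 CPM. Rpl3-ps1 took 3620 and 3760 reads and its parent gene Rpl3 117 and 88, so the levels of such parent genes are uncertain. Of the 6565 and 3419 reads assigned to Actb, 636 and 570 lay on complete models (annotated, or of the unannotated classes NIC and NNC). The 10 highest genes took 6.10% of annotated-gene reads in replicate 1 and 5.83% in replicate 2.

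**Figure D1:**
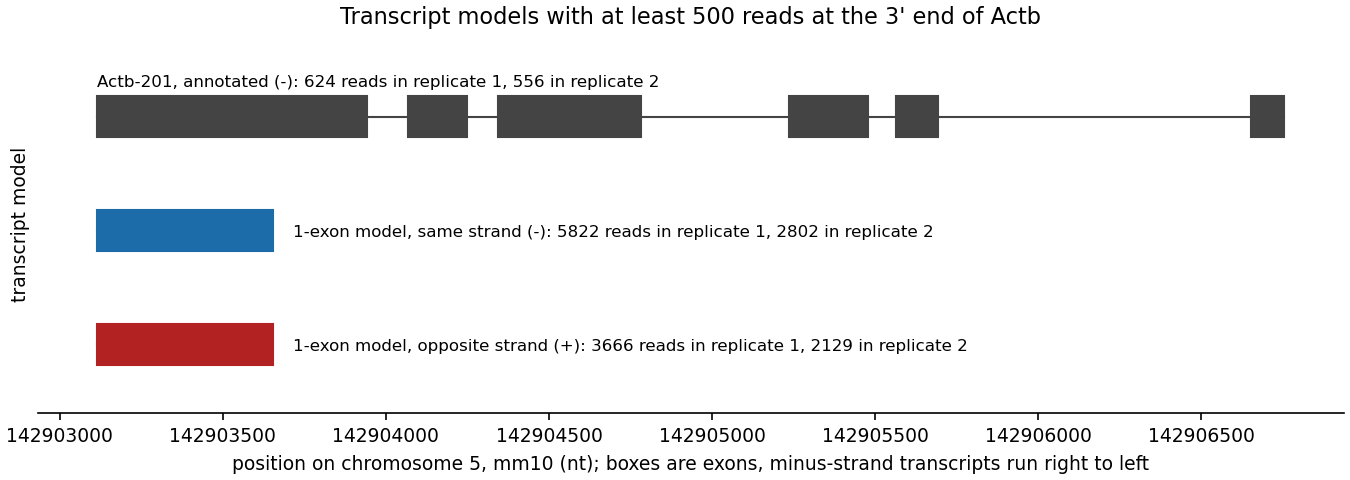
Map of 3 transcript models at the 3' end of Actb on mm10 chromosome 5, with boxes for exons and the position in nt on the x axis. The sense and antisense 1-exon models share their ends, 142903115 to 142903654, inside exon 6 of Actb-201.

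Regulators of muscle identity were expressed, including myogenin. Of 12 myogenic transcription factors, 10 had reads in both libraries, and their levels summed to 1169.8 ± 53.5 CPM. Myog, the myogenin gene that acts as myoblasts enter differentiation, was the highest at 597 ± 43.8 CPM. The determination factors Myf5 and Myod1 stood at 181 ± 138 and 165 ± 15.5 CPM. Mef2a, Tcf12 and Mef2d, cofactors and partners of the MyoD family, had 40.1 ± 0.0339, 39.5 ± 2.84 and 18.9 ± 6.58 CPM. Six4 had 6.65 ± 1.57 CPM and Mef2c 1.98 ± 0.850 CPM. Pax7, which marks satellite cells, had 6 and 3 reads, and Pax3 and Myf6 had 0. Myf5 was higher in replicate 1 (log2 ratio of replicate 2 over replicate 1 -1.73, adjusted p 1.05e-16 by an exact binomial test), the 1 call among 8 tested members and also the 1 call adjusted over the list alone. On complete models Myf5 had 76 and 36 reads.

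Inhibitors of myogenic differentiation were present at a like total, 1163 ± 126 CPM for 9 of 11 genes with reads in both libraries. Id3, a dominant-negative partner of basic helix-loop-helix factors, made up most of it at 726 ± 71.7 CPM. Its relatives Id1 and Id2 had 103 ± 17.2 and 98.6 ± 15.1 CPM, the repressor Snai2 119 ± 25.6 CPM and the Notch target Hes1 76.7 ± 6.72 CPM. Zeb1, Heyl and Msc had mean levels of 14.7, 10.8 and 5.35 CPM, and Hey1 had 8 and 7 reads. Twist1 and Mdfi had 0 reads. None of the 8 tested members was called, over all genes or adjusted over the list alone.

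Genes of the myoblast surface, of fusion and of the desmin filament were all read in both libraries, 13 of 13, and summed to 2665 ± 331 CPM. Des, the muscle intermediate filament desmin, led at 1391 ± 356 CPM. The heparan sulfate proteoglycan Sdc4 had 408 ± 113 CPM, M-cadherin (Cdh15) 218 ± 19.9 CPM and the fusion protein myomaker (Mymk) 146 ± 8.89 CPM. Its partner myomixer (Mymx) had 21.6 ± 6.71 CPM. Itga7, Ncam1, Vcam1, Dag1 and Cdh2, which encode adhesion receptors, had mean levels of 119, 119, 76.9, 72.5 and 59.6 CPM. Sdc3, Met and Cav3 had 27.4, 3.37 and 2.03 CPM. Des was higher in replicate 2 (log2 ratio 0.53, adjusted p 5.84e-14) and Sdc4 higher in replicate 1 (-0.57, adjusted p 1.26e-04), with 3 of 11 tested members called when adjusted over the list alone. Sdc4 was not called on complete-model reads.

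Contractile genes of differentiated muscle were read as well, 24 of 30 in both libraries and 4 in neither, with a sum of 2712 ± 342 CPM. Skeletal alpha-actin (Acta1) had 587 ± 42.4 CPM, the slow and cardiac troponin C gene Tnnc1 401 ± 155 CPM, the fast regulatory light chain Mylpf 293 ± 40.8 CPM and cardiac alpha-actin (Actc1) 274 ± 9.38 CPM. The adult and perinatal myosin heavy chains Myh2, Myh4 and Myh8 and the M-band gene Myom1 had 0 reads. Tnnc1 (-0.81, adjusted p 5.90e-09) and the fast troponin C gene Tnnc2 (-0.57, adjusted p 0.0309) were higher in replicate 1. These were the 2 calls among 21 tested members, and 3 were called when adjusted over the list alone.

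**Figure D2:**
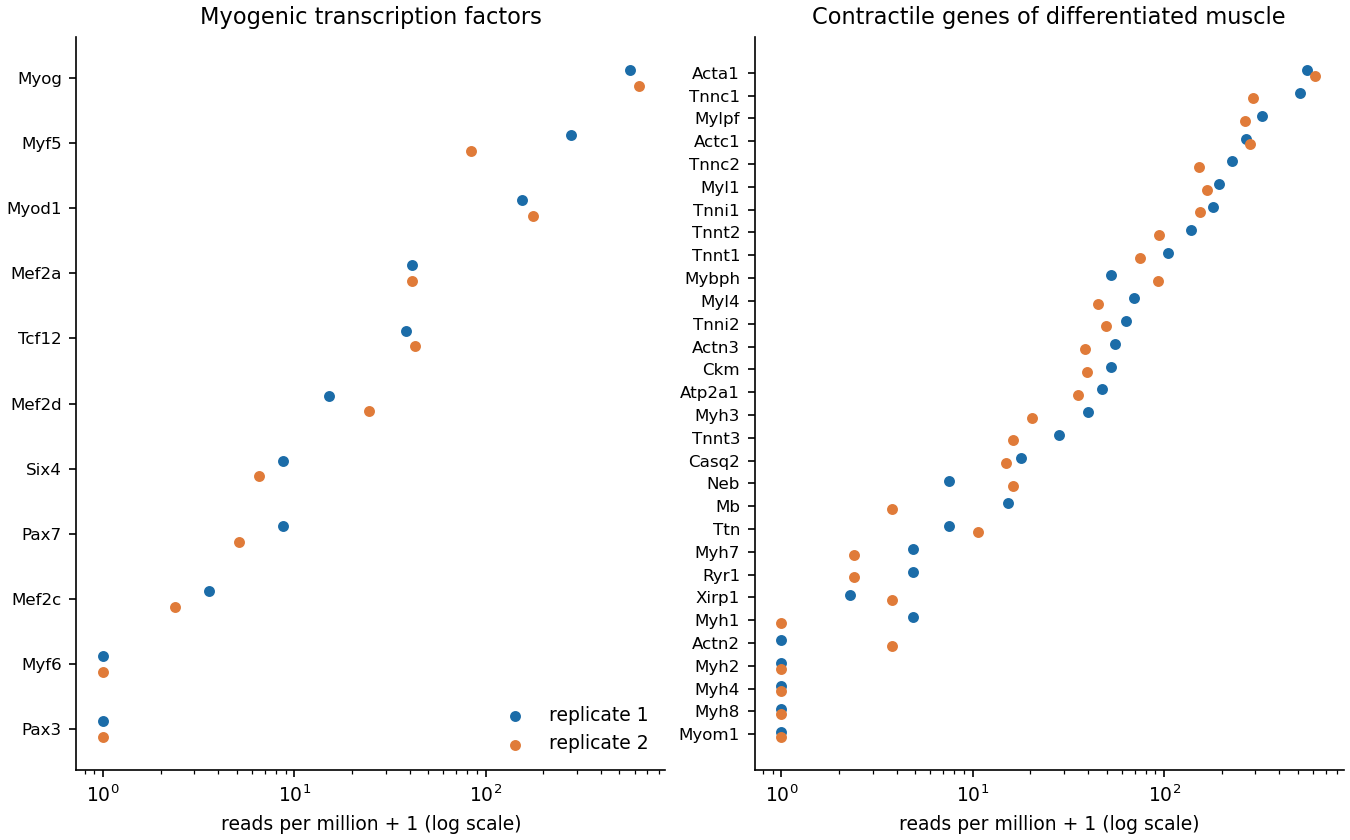
Levels of 11 of 12 myogenic transcription factors (left) and 30 contractile genes (right), as CPM + 1 on a log axis, with a point for each of the 2 replicates; genes without reads lie at 1. Myog and Acta1 lead their panels, and Myf5 shows a wide gap between replicates, 215 and 60 reads.

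The non-muscle and smooth muscle cytoskeleton made up the largest of the 23 sums, 43607 ± 43.9 CPM over 25 genes, all read in both libraries. Besides Actb, Actg1 and Vim, the alpha-tubulin gene Tuba1b had 3304 ± 289 CPM. Of the 25, 8 were higher in replicate 2 and 3 in replicate 1, and 13 were called when adjusted over the list alone. With either alternative scaling the counts were 7 and 3. Actb (log2 ratio -0.84, adjusted p 2.34e-173) was not called on complete-model reads. Extracellular matrix genes, all 28 of them read in both libraries, summed to 7675 ± 436 CPM. The collagen-binding protein Sparc had 2144 ± 59.4 CPM, the prolyl hydroxylase subunit P4hb 1594 ± 128 CPM, the proteoglycan biglycan (Bgn) 1114 ± 163 CPM and the fibrillar collagen Col3a1 396 ± 25.6 CPM. Bgn was higher in replicate 2 (0.30, adjusted p 0.00144) and the metalloproteinase inhibitor Timp2 higher in replicate 1 (-0.69, adjusted p 0.00552) among 27 tested, with 2 called when adjusted over the list alone. Timp2 was not called on complete-model reads.

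Cell cycle genes were all expressed, 26 of 26, with a sum of 5346 ± 646 CPM. The ribonucleotide reductase subunit Rrm2 had 1058 ± 115 CPM, the D-type cyclin Ccnd3 426 ± 88.5 CPM, the anaphase activator Cdc20 420.4 ± 53.3 CPM and survivin (Birc5) 305 ± 12.7 CPM. Ccnd3 was higher in replicate 2 (0.43, adjusted p 0.00926), the 1 call of 26, and 2 were called when adjusted over the list alone. Cell cycle inhibitors summed to 1029.6 ± 39.01 CPM, with 6 of 8 read in both libraries. Cdkn1a, which encodes the CDK inhibitor p21, had 712 ± 36.1 CPM and Trp53, the p53 gene, 232 ± 20.6 CPM. Cdkn2c, Cdkn1b, Cdkn1c and Rb1 had mean levels of 48.8, 19.7, 15.9 and 1.34 CPM, and Cdkn2a and Cdkn2b had 0 reads. None of 5 tested inhibitors was called, and 1 was called when adjusted over the list alone.

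Glycolysis genes were expressed at 18026 ± 1959.6 CPM over 15 genes. After Pkm and Eno1, the lactate dehydrogenase gene Ldha had 3343 ± 332 CPM and the aldolase gene Aldoa 2033 ± 277 CPM. Pkm, Eno1, Ldha, Aldoa, Pgk1 and Pgam1 were higher in replicate 2, with log2 ratios of 0.24, 0.22, 0.20, 0.28, 0.35 and 0.24, and 7 of 15 were called when adjusted over the list alone. Pgam1 was not called with either alternative scaling, without the read filter or on complete-model reads. Gapdh had 9 and 17 reads, while its 19 processed pseudogenes had 2544 and 2567, so its own level and the sum of the list are uncertain. Translation factors and ribosomal stalk genes summed to 19201 ± 73.1 CPM, with 12 of 13 read in both libraries and 0 reads on Eef1a2, the form of adult muscle and neurons. The elongation factor genes Eef2, Eef1g, Eef1d and Eef1b2 had 1679 ± 94.8, 714 ± 78.7, 515 ± 54.7 and 473 ± 31.2 CPM. Tpt1 had 1184 ± 34.0 CPM, Rack1 853 ± 87.6 CPM, the helicase Eif4a1 438 ± 1.65 CPM and the poly(A)-binding protein Pabpc1 204 ± 44.7 CPM. Eef1a1 was higher in replicate 2 (0.14, adjusted p 0.00372), but not with either alternative scaling. Rpsa (-0.26) and Rplp1 (-0.39) were higher in replicate 1, and 6 members were called when adjusted over the list alone. On complete-model reads Rpsa had 975 and 1006 reads, turned to a log2 ratio of 0.0704 and was not called. The 13 mitochondrially encoded mRNAs summed to 154 ± 7.76 CPM. The oxidase subunit mt-Co1 had 88.2 ± 3.33 CPM, mt-Nd1 16.6 ± 5.82 CPM and mt-Cytb 15.5 ± 3.58 CPM, while mt-Atp6, mt-Co3, mt-Nd5, mt-Co2, mt-Nd2 and mt-Nd4 had mean levels of 8.08, 6.65, 6.05, 4.71, 4.57 and 1.98 CPM. Over both libraries mt-Nd4l and mt-Nd6 had 1 read each, and mt-Nd3 and mt-Atp8 had 0 reads. None of 5 tested was called, over all genes or adjusted over the list alone. Mitochondrial models took 150 and 130 reads, 0.0189% and 0.0177% of all reads, so most of these levels rest on few reads. Whether they reflect the RNA of the cells or reads lost before counting was not tested.

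Splicing regulators were read in both libraries for 20 of 22 genes and summed to 4698 ± 168 CPM. The RNA-binding proteins Hnrnpk and Hnrnpa1 had 1098 ± 29.0 and 1007 ± 63.4 CPM, and the splicing factors Srsf3 and Srsf2 538 ± 15.4 and 428 ± 1.62 CPM. No member was called, and 2 were called when adjusted over the list alone. The regulator Qk was called higher in replicate 1 with either alternative scaling, and Mbnl2 higher in replicate 2 at a minimum of 50 reads. Of 15 long non-coding RNAs, 10 were read in both libraries, with a sum of 2692 ± 191 CPM. The nuclear RNA Malat1 had 1904 ± 29.9 CPM, the imprinted RNA H19 427 ± 184 CPM and the snoRNA hosts Gas5 and Snhg8 174 ± 33.2 and 62.3 ± 3.93 CPM. H19 was higher in replicate 1 (-0.90, adjusted p 5.26e-12), the 1 call of 9 tested and the 1 call adjusted over the list alone. Meg3, Rian, Mirg, Mir17hg and Kcnq1ot1 had 0 reads. Imprinted genes summed to 231 ± 0.668 CPM, with 6 of 10 read. Mest had 147 ± 8.96 CPM, Sgce 40.2 ± 3.82 CPM and Peg3 22.7 ± 0.801 CPM, while the growth factor Igf2 had 7.25 ± 4.38 CPM, Ndn 6.65 ± 1.57 CPM and Igf2r 6.56 ± 5.36 CPM. Dlk1, Peg10, Plagl1 and Grb10 had 0 reads. None of 6 tested was called, over all genes or adjusted over the list alone.

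Stress and immediate early genes, 18 of 18 read in both libraries, summed to 7272 ± 109.8 CPM. The member Hspa8 had 119 and 139 reads, while its near-identical pseudogene Gm15459 had 3485 and 4063. The level of Hspa8, the sum and the order of the highest members are therefore uncertain. The chaperone Hsp90ab1 had 2356 ± 50.5 CPM, the autophagy receptor Sqstm1 946 ± 173 CPM, the endoplasmic reticulum chaperone Hspa5 879.9 ± 149 CPM and the small heat shock protein Hspb1 867 ± 26.5 CPM. Sqstm1 (0.38) and Hspa5 (0.35) were higher in replicate 2 and the metallothionein Mt1 (-0.69) in replicate 1 among 16 tested, and 4 were called when adjusted over the list alone.

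Markers of 7 other cell types were low apart from some progenitor markers. Of 45 marker genes, 10 had reads in both libraries and 29 had none. Fibro-adipogenic progenitor markers summed to 480.4 ± 21.2 CPM, from the surface proteins Ly6a (332 ± 19.97 CPM) and Cd34 (147 ± 41.1 CPM) with Pdgfra at 1.34 ± 0.0642 CPM, and 1 was called when adjusted over the list alone. Both Ly6a and Cd34 are also made by muscle progenitors. Cartilage and bone markers summed to 64.0 ± 19.1 CPM, most of it the chondrocyte factor Sox9 (58.0 ± 19.8 CPM) with 5 and 3 reads of Runx2 and 1 read of Sp7, and 1 was called when adjusted over the list alone. Neural and glial markers summed to 63.6 ± 2.10 CPM, nearly all from the tubulin Tubb3, with 1 read of Mbp. Epithelial markers summed to 37.3 ± 5.77 CPM, mainly the keratin Krt14 with 1 read of Krt18, and adipocyte markers to 23.4 ± 0.177 CPM, from Pparg and Cebpa. Blood cell markers summed to 6.09 ± 3.13 CPM, from 3 and 2 reads of Cd68 and 0 and 2 each of Lyz2 and Csf1r. For endothelial markers 1 read of Pecam1 was the only one, a mean of 0.692 CPM.

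The second comparison was between the 2 biological replicates, and its p-values measure these 2 libraries, not a condition. Gene levels followed each other closely, with Pearson r 0.938 and Spearman rho 0.941 of log2(CPM + 1) across the 14198 genes read in either library; genes are not independent replicates. Of 8940 genes tested by a two-sided exact binomial test, 356 differed after adjustment and 1246 at an unadjusted p under 0.05. Of the 356, 124 were higher in replicate 2 and 232 in replicate 1, a split that moved to 82 and 303 with TMM scaling and 78 and 315 with DESeq2 size factors. At least 2-fold differences numbered 71, of which 9 were higher in replicate 2 and 62 in replicate 1. The biological coefficient of variation was 0.136. The chi-square of all tested genes was 2.49 times its degrees of freedom. The binomial test allows for counting error alone, so genes with many reads could be called at small log2 ratios within this wider spread.

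**Figure D3:**
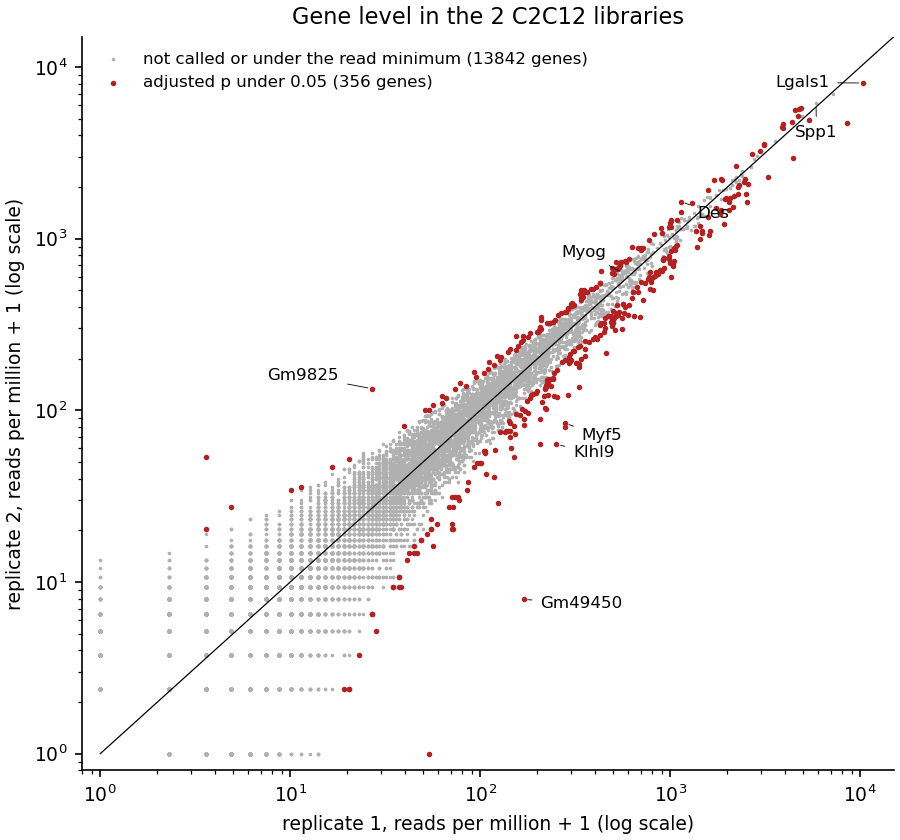
CPM + 1 of each annotated gene in replicate 1 against replicate 2, both axes logarithmic, with the 356 genes that differed in red and the others in grey. Most genes lie along the diagonal, and the red points spread to either side of it.

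Among genes with at least 2-fold differences, the 6 with the smallest adjusted p in each direction included Myf5 and the processed pseudogenes Gm9825 and Gm7335. Spry2 (ENSMUSG00000022114.5; chromosome 14, 105891947 to 105896819), a feedback inhibitor of receptor tyrosine kinase signalling, was higher in replicate 1 with 214 and 57 reads (log2 ratio -1.80, counting SE 0.21, adjusted p 2.12e-17). Of its reads 1 and 0 lay on complete models. Klhl9 (chromosome 4, 88718292 to 88722465), a ubiquitin ligase adaptor, had 194 and 45 reads (-1.998, adjusted p 4.15e-18). The zinc transporter Slc39a1 (chromosome 3, 90248172 to 90253612) had 255 and 98 reads (-1.28, adjusted p 1.82e-12), with 14 and 8 on complete models, where it was not called. Gm49450 had 130 and 5 reads (-4.47) and Gm49164 354 and 155 (-1.09), with 0 of the latter on complete models. Higher in replicate 2 were Gm9825 (20 and 96 reads, 2.33) and Gm7335 (2 and 38, 4.04) and the adenosine deaminase gene Ada (chromosome 2, 163726584 to 163750239; 3 and 19 reads, 2.58, counting SE 0.84, adjusted p 0.0136). Fam172a (1.52), Rcbtb2 (1.37) and Fam118b (1.04) followed. Rcbtb2 and Fam118b lost their calls without the read filter and on complete-model reads. Summed over the gene's own models and all same-strand models that overlapped or touched it, Gm9825 had 138 and 129 reads, Gm7335 51 and 53 and Gm49450 4597 and 4790.

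As groups, contractile genes were lower and cell cycle genes higher in replicate 2. The median log2 ratio of the 24 contractile genes read in both libraries was -0.41, at percentile 0.03 of 10000 random lists matched on mean expression. Of these 24 genes, 6 were higher in replicate 2. On complete-model reads the median of 21 members was -0.18, at percentile 1.335. The 26 cell cycle genes had a median of 0.27 at percentile 99.87, with 23 of 26 higher in replicate 2. On complete-model reads the median of 25 members was 0.22, at percentile 97.905. For all reads, adjusted over the 17 lists with enough members, the two-sided p against random lists was 0.0102 for the contractile and 0.0221 for the cell cycle list. Genes of a list are not independent replicates. The other 15 lay between percentiles 8.65 and 97.12, the highest being glycolysis with a median of 0.22. Replicate 1 also had more reads on 1-exon models than replicate 2, 15.7% against 11.8%.

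Transcript models were shorter and more fragmentary in replicate 1. The read-weighted median model length was 1495 nt with 5 exons in replicate 1 and 1675 nt with 6 exons in replicate 2. Models of 1 exon took 15.7% of reads in replicate 1 (Wilson 95% interval 15.6 to 15.8) and 11.8% in replicate 2 (11.7 to 11.9). Incomplete splice matches that keep the 3' end took 6.74% (6.68 to 6.79) and 5.53% (5.48 to 5.58). Those that keep the 5' end took 1.55% (1.53 to 1.58) and 1.66% (1.63 to 1.69).

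Annotated transcripts carried most reads. The class of annotated structures took 75.5% (Wilson 95% interval 75.4 to 75.6) and 79.3% (79.2 to 79.4) of reads in the 2 libraries, a mean of 77.4 ± 2.67%. Incomplete splice matches took 9.33 ± 1.47%. Among unannotated structures, the authors' class NIC, named for known splice sites in an unannotated combination, took 3.33 ± 0.325%. Their class NNC, named for an unannotated splice site, took 3.71 ± 0.398%. The classes are given as deposited, and the NIC structures of Sfr1, Hnrnpk and Capn2 described here used a site that GENCODE M21 does not hold. Models in the genomic class took 4.25 ± 1.47%, antisense models 1.73 ± 0.421% and intergenic models 0.225 ± 0.0294%. Processed pseudogenes took 4.84% and 4.59% of annotated-gene reads.

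**Figure D4:**
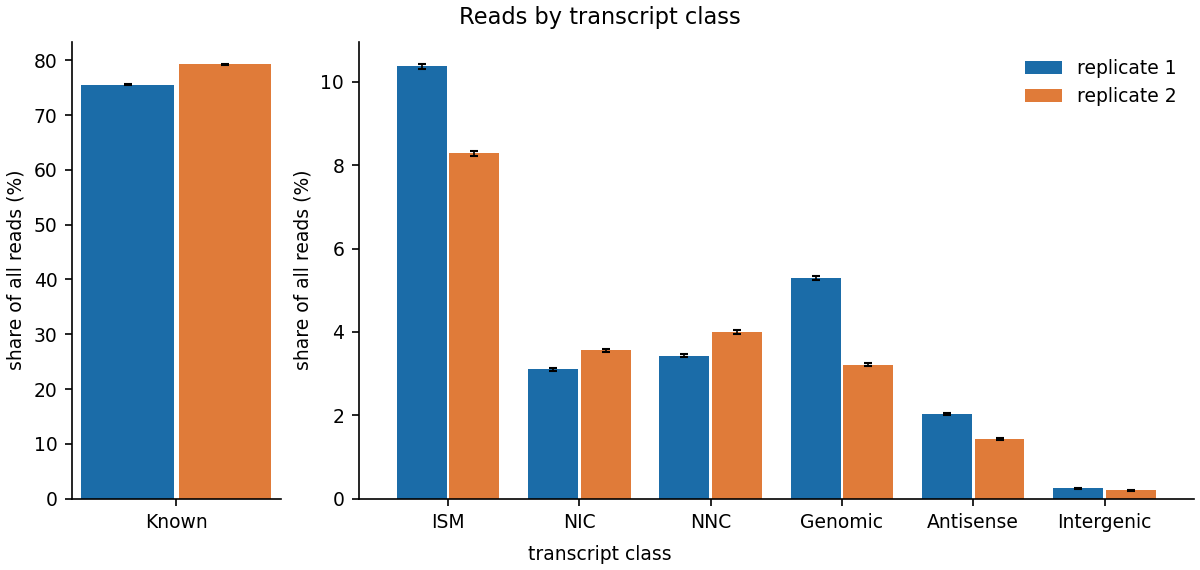
Share of reads in each transcript class for replicates 1 and 2, in 2 panels with different y scales, with Wilson 95% intervals as error bars. Annotated models took 75.5% and 79.3% of reads, and incomplete, genomic and antisense models took larger shares in replicate 1.

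Structures with several reads were shared by the libraries. Of models with at least 5 reads in one library, the other held 99.4 ± 0.0937% of annotated, 96.6 ± 2.32% of incomplete, 97.2 ± 0.489% of NIC and 97.4 ± 0.776% of NNC models, as the mean of both directions. Unannotated NIC or NNC structures with several exons numbered 27895 and 30322, of which 7982 were in both libraries and 820, in 623 genes, had at least 5 reads in each. Unannotated splice sites of NNC structures with that support lay within 6 nt of an annotated site in 59.1% of cases (231 of 391, Wilson 95% interval 54.1 to 63.8). For NNC structures with 1 read the share was 40.7% (40.2 to 41.2).

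The best supported unannotated structures took most of the reads assigned to several genes. Alignments of the reads were not examined, so errors of alignment or differences from the reference genome are not excluded for them. In Oaz1, the antizyme gene of polyamine control, a structure at chromosome 10, 80826656 to 80829284, had 1496 and 1368 reads, 91.8 ± 0.563% of the gene's reads. It differed from Oaz1-201 only by the lack of a 4-nt annotated gap at 80828292 to 80828295, and it had no unannotated intron. In the prohibitin gene Phb2, a structure without the annotated 6-nt exon 124716425 to 124716430 took 92.7 ± 2.90%. In the protease gene Capn2, the lack of the 12-nt exon 182482536 to 182482547 marked 81.3 ± 1.26% of reads, and in the septin gene Sept7 the lack of the 5-nt exon 25265302 to 25265306 marked 75.9 ± 2.5%. A pair of structures of Hnrnpk without the 16-nt exon 58393853 to 58393868 took 34.9 ± 1.40% and 23.3 ± 1.54%. Their intron across it ended 16 nt short of the annotated site, so the neighbouring exon gained 16 nt. In Capn2 the neighbouring exon gained 17 nt in the same way. Whether the bases of the short exon were aligned to the neighbouring exon was not tested. The structure of Sfr1 had an added 49-nt intron, 47732753 to 47732801, and 71.4 ± 1.15% of reads. The structure of the chaperonin gene Cct6a used the intron 129794561 to 129844936 in 61.4 ± 1.76%, where Cct6a-202 has 129794500 to 129844969. In the nucleoside transporter gene Slc29a1 a structure took 24.7 ± 3.21%, and in basigin (Bsg) 19.5 ± 1.5%.

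Most genes used 1 main transcript. Among 4281 genes with at least 20 complete-model reads in each library, the most used transcript had a median share of 89.1%, and it reached 90% in 2034 genes. In 933 genes (21.8%) at least 2 transcripts reached 10% in both libraries, and in 131 genes at least 3 did. At a 20% share, 428 genes had at least 2. The most used transcript was unannotated in 110 genes. It was the same in both libraries for 4153 genes.

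Among the listed isoform genes, pyruvate kinase appeared mainly in its M2 form, and Myl6, Tpm2 and Bin1 were divided between transcripts. Of 42 such genes, whose levels summed to 18083 ± 539 CPM, 3 were called between libraries and 7 when adjusted over the list alone, and 27 had enough reads for shares. Pkm-201, with the 167-nt exon 59675568 to 59675734 that marks the M2 form of pyruvate kinase, took 81.9 ± 0.104% of complete Pkm reads. Pkm-202, with the 167-nt M1 exon 59675029 to 59675195, took 10.8 ± 1.18%. For the tropomyosins, Tpm1-216 took 68.7 ± 2.57% and Tpm1-211 10.5 ± 0.332%, Tpm3-201 81.5 ± 2.48% and Tpm4-201 96.3 ± 0.216%. In Tpm2 an unannotated structure took 45.2 ± 1.88%, Tpm2-202 27.0 ± 1.22% and Tpm2-203 19.2 ± 2.37%. The unannotated structure has the 76-nt exon 43518644 to 43518719, where Tpm2-203 has the 76-nt exon 43519003 to 43519078. The myosin light chain gene Myl6 was split between Myl6-201 (48.4 ± 1.37%) and Myl6-206 (41.1 ± 0.893%), which differ by the 45-nt exon 128491720 to 128491764. Capzb, an actin capping subunit, used Capzb-204 in 78.9 ± 2.88% and Capzb-203, which differs by the 113-nt exon 139288861 to 139288973, in 15.9 ± 4.23%. The membrane-shaping gene Bin1 used Bin1-205 in 50.1 ± 5.27% and Bin1-206 in 29.8 ± 0.304%, which differ by the 72-nt exon 32431671 to 32431742. The phosphate carrier Slc25a3-201 took 78.5 ± 0.200%, Cdc42-202, of a small GTPase, 97.0 ± 1.76%, and H13-204, of signal peptide peptidase, 75.9 ± 0.276%. Rps24-210, of a ribosomal protein, took 82.6 ± 2.66%.

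**Figure D5:**
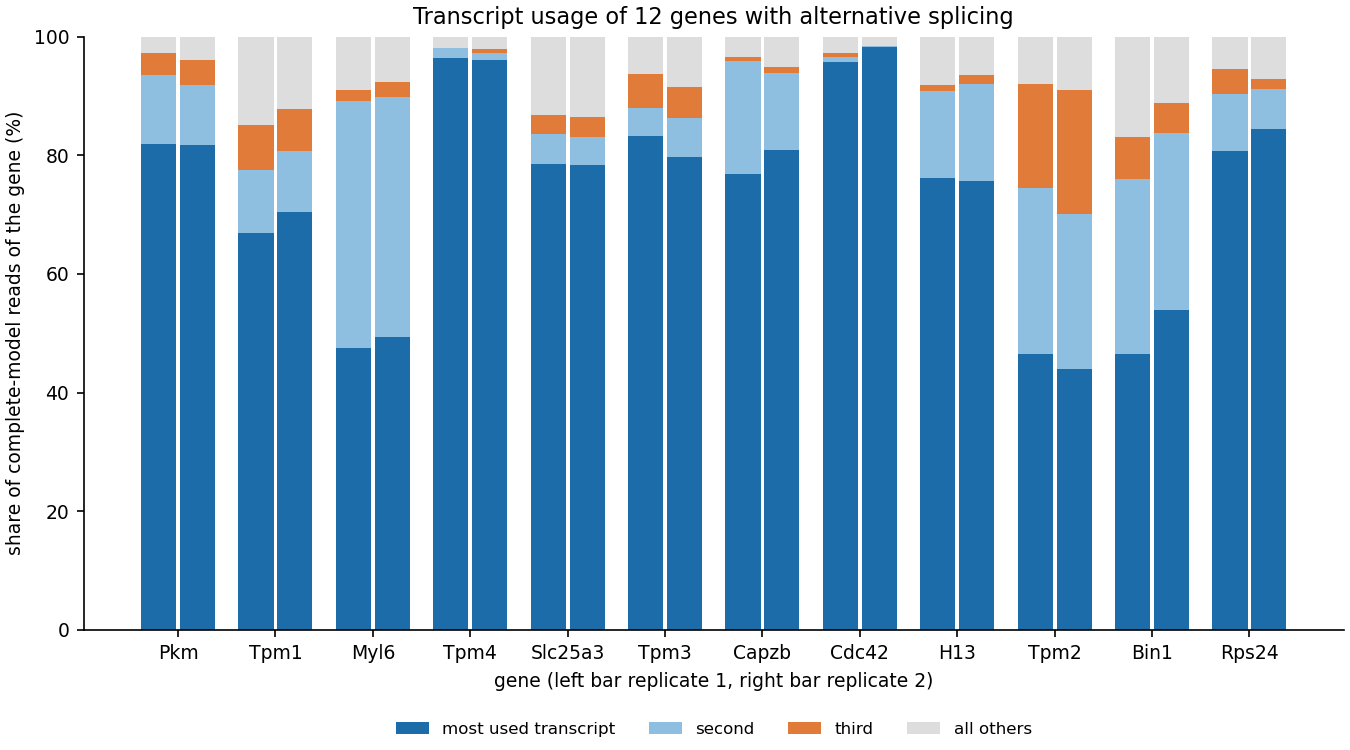
Share of complete-model reads of the 3 most used and all other transcripts for 12 genes, as stacked bars with replicate 1 on the left and replicate 2 on the right of each pair. Tpm4 and Cdc42 used nearly 1 transcript, and Myl6, Tpm2 and Bin1 were divided.

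Isoform use differed between the libraries in 4 of 4281 genes by a two-sided Fisher's exact test after adjustment, and in 167 at an unadjusted p under 0.05. With incomplete models included, 108 genes differed, 3 of them among the 4. S100a4-201, of a calcium-binding protein, took 628 reads against 406 of other transcripts in replicate 1 (60.7%) and 495 against 139 in replicate 2 (78.1%, adjusted p 5.70e-10). Ftl1-201 had 96.5% and 98.1% (adjusted p 0.000328), and Qsox1-208, of a sulfhydryl oxidase, 78.7% and 51.0% (adjusted p 0.00811). In Mxra8 an unannotated transcript had 0 of 21 reads and 65 of 88, but the same intron chain stood in the incomplete class in replicate 1, and with that class included its share moved by 5.92 points (adjusted p 1). Ak6-202 had 78.5% and 57.1% and was not called (adjusted p 0.0699).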

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

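The tests of reads split between overlapping genes and of genes with under 10 complete-model reads were chosen only after the result was seen. The sum of the former was widened after a run by coordinates alone, which had left out models of a gene beyond its annotated bounds, had given 8 of 71 genes (11.3%).

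Reads outside annotated genes are not part of the comparisons of the report, and signal there stood above the limit that a count of 0 allows; the 5 loci with the highest lower count are named here. On the strand opposite to Actb, a 1-exon model at chromosome 5, 142903115 to 142903654, had 3666 reads in replicate 1 and 2129 in replicate 2, 0.463% and 0.290% of all reads. Opposite to Cavin1, which encodes a coat protein of caveolae, a model at chromosome 11, 100956733 to 100958474, had 1310 and 1140 reads. Opposite to the septin gene Sept2, a model at chromosome 1, 93507713 to 93509733, had 390 and 210 reads. An intergenic model at chromosome 13, 21812147 to 21820119, on the strand of the histone gene Hist1h4m that it overlaps, had 177 and 195 reads. Another at chromosome 17, 34995913 to 35000439, 548 nt from the tRNA synthetase gene Vars, had 173 and 209 reads. At least 10 reads in both libraries were found at 122 antisense and 14 intergenic loci.

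The antisense reads may be sense fragments given the wrong strand. Of 26588 antisense-model reads, 98.4% lay on 1-exon models, and 71.6% lay inside an exon of the opposite strand with an end within 20 nt of that transcript's 3' end (63.7% without the Actb locus), against 2.01% at the 5' end. At Actb the sense 1-exon model with the same ends had 5822 and 2802 reads. Priming of antisense RNA at A-rich sequence stays open. The median A share past the 3' end was 0.55, and 1 at the Actb model in both libraries, as such priming would give. Sequence was at hand for 392 of 556 models (70.5%), under the 80% that the test required to decide. That minimum was not in the prediction written beforehand, which the median met. For a sense fragment the same stretch lies just before its start, where 1693 sense 1-exon models had a median T share of 0.25. A wrong strand alone would predict like values for both sets of models, which were not matched. No biological explanation was tested.

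Transcript length may be one source of the difference in the 356 genes. Those higher in replicate 2 had a median transcript length of 2113.5 nt, 2.29 times the 923.5 nt of those higher in replicate 1. Both medians lay below the 2506.5 nt of all tested genes. The trend over all tested genes was not steady, with median log2 ratios of -0.16, 0.12, 0.14, 0.10 and 0.01 from the shortest to the longest of 5 equal bins, so length alone is not shown to account for the calls. Complete models argue against fragment content as the main cause for the 331 genes with at least 10 complete-model reads. For these the median size of the log2 ratio on complete models was 0.979 of its value on all reads, and 319 kept their direction. Over all 356 genes it was 0.940, and 45 of 71 stayed at 2-fold. Calling anew on complete models shared 245 of the 356 calls and 29 of the 71 2-fold calls. The genes were called on reads that include the complete ones, so part of this agreement is built in. The complete classes also do not establish that each model spans a whole transcript. For the 25 genes with under 10 complete-model reads, such as Spry2 and Gm49164, a median of 95.8% of reads lay on incomplete or genomic models, and fragment content stays open. Reads split between overlapping genes are argued against for most of the 71 genes, since their summed loci held no reads beyond their own. On summed loci 6 of 71 (8.45%) fell under 2-fold, among them Gm9825, Gm7335 and Gm49450. The fall of Gm49450 cannot show a split, since its 130 and 5 reads are a small part of a sum of 4597 and 4790. The design gives no biological explanation, and none was tested.

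The contractile list lay low and the cell cycle list high in replicate 2. With random lists matched on transcript length as well, their percentiles were 0.03 and 99.34, which argues against length alone as the cause. On complete models they were 1.335 and 97.905 with medians of -0.18 and 0.22, so fragment content as a cause stays open for both, since the contractile median moved toward 0 on 21 members, while the cell cycle median kept most of its 0.27 but lay just outside the central range, short of the bound set beforehand to exclude it. A difference in the state of the replicate cultures is one hypothesis that these tables leave untested. No biological explanation was tested.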

How the results depend on the processing

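No test in this part was chosen only after the result was seen; every alternative was planned. A count was taken to hold within 1.5 times its value, a level within 1 SD of the libraries and a test on its side of the threshold; the correlation and the coefficient of variation, which have no such spread, counted as moved with any change in the digits printed. By these rules 47 values of the main results held, 14 moved and none reversed. Part of this was fixed in advance, here and for the other values below. A level or share that is the mean of the 2 libraries cannot move by 1 SD when a replicate is left out. Counts and levels could only hold or move, so a reversal was possible for log2 ratios and changes in share alone. The correlation across genes was 0.816 with a pseudocount of 0.1, 0.977 with 10 and 0.948 for genes with at least 10 reads. Genes higher in replicate 2 numbered 82 with TMM and 78 with DESeq2 size factors, since both scale replicate 2 down. The coefficient of variation was 0.134 at 50 reads, and the median of DESeq2's gene-wise estimates gave 1e-04 on the same scale, the square root of that tool's lower bound on dispersion. The annotated share rose to 86.2% among transcripts with at least 5 reads. NNC models seen in the other library were 66.6% from 2 reads, 100% from 20 reads and 0% by identifier, because unannotated identifiers belong to a single library. Genes with at least 2 isoforms numbered 428 at a 20% share, a stricter limit. With incomplete models, 108 genes differed in isoform use, 3 of them shared with the 4 called; the cause was not tested. Myogenic factors summed to 1086 CPM on complete models, which leave out incomplete reads.

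Of the other values, which include the named genes that could be tested, 636 held, 27 moved, 20 lost a call, 13 gained one and 2 reversed. On complete models Rpsa turned to a log2 ratio of 0.0704 without a call (adjusted p 0.714), and Hsp90ab1, not called on all reads, was called higher in replicate 2 (0.22, adjusted p 0.0369); the cause was not tested. Actb, Sdc4, Timp2, Rpl3-ps1 and Pgam1 lost their calls on complete models, and Eef1a1, Rpl3-ps1, Tuba1b and Pgam1 with both scalings. Pgam1 also lost it without a filter. Calls were gained by Ftl1 with both scalings and on complete models, Rack1 with both scalings, Rrm2 at 50 reads, Cd34 at 50 reads and on complete models, and Sparc and Eef2 on complete models. Among list members outside this count, Qk and Rps24 gained calls with both scalings, Mt2 with both scalings, at 50 reads and on complete models, and Mbnl2, Cdc42 and Cnn3 at 50 reads, while Myl12a lost its call without a filter and Tuba1a on complete models. Rcbtb2 and Fam118b had adjusted p values of 0.0550 and 0.0564 without a filter, and 0.0928 and 0.132 on complete models. Slc39a1 had 0.718 on complete models and Mxra8 1 with incomplete models. Ak6 gained its call at 50 reads (0.0480) and with incomplete models (0.0156), and glycolysis reached percentile 97.57 with a pseudocount of 10. No paired analysis was possible because there is 1 group. Leaving out a replicate gave no value for the correlation, the differing genes, the dispersion, the isoform test, the list differences or models seen. Depth limits small changes: 34.5% of 2-fold changes simulated with counting error alone were called.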

Other observations

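No test in this part was chosen only after the result was seen, but the test of T-rich starts was prompted by the A-rich sequence past the antisense Actb model.

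Some abundant genes, such as Hspa8, Rpl3, Rps2 and Gapdh, had fewer reads than a processed pseudogene of theirs. Reads of near-identical parent mRNAs may account for most processed pseudogene reads, since 96.1% of the 70632 processed pseudogene reads lay on pseudogenes with a protein-coding transcript at least 98% identical over 90% of their length. Of 700 pseudogenes with reads, 478 (68.3%) had such a transcript, against 5.55% of 9536 without reads. Gm15459 had 3485 and 4063 reads against 119 and 139 for Hspa8. Rps2-ps10 had 2761 and 2691 reads against 31 and 27 for the ribosomal protein gene Rps2, and Gm13394 had 2293 and 2349 against 9 and 17 for Gapdh. In all, 26 pseudogenes with at least 100 reads exceeded their closest coding gene.

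Several of the best supported unannotated structures lack a very short exon, as in Phb2, Sept7, Capn2 and Hnrnpk. The Oaz1 structure lacks no exon, only the 4-nt annotated gap. These cases led to the hypothesis that short exons or gaps are passed over. Beyond the 10 named structures it held for 12 of 113 (10.6%) with at least 20 reads in both libraries, so it is unlikely to account for most of those 113. For the named structures, which prompted it and were left out of the test, it stays open.

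Priming inside T-rich sequence was tested as a possible explanation of 1-exon fragments at annotated 3' ends. The median T share before the start of 1693 such models was 0.25, as in random windows of the same exons, which argues against it for most of them. A T share of at least 0.5 was found for 12.5% of models and 7.32% of windows, and those models held 40.3% of the 35924 reads. Much of that read share is the sense 1-exon model of Actb, with 5822 and 2802 reads. The sequence before its start is the stretch with an A share of 1 past the antisense model. The read share without Actb was not computed.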
